A study of Homo sapiens with 9 samples.

How the data were processed

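Messenger RNA was measured on 9 two-colour oligonucleotide arrays of SKbr3 cells, a HER2-amplified human breast cancer line. Each array compared cells given an siRNA against TRMT12 with cells given a control siRNA. There were 3 TRMT12 siRNAs, here numbered 1 to 3 as in the labels, and 3 hybridisations for each. In 2 of the 3 hybridisations the knockdown sample carried Cy5, and in the remaining array the dyes were exchanged. Per the labels' protocols, RNA was amplified by in vitro transcription, coupled to the dyes and hybridised to spotted oligonucleotides of a commercial human set. The series text describes the same control siRNA for every comparison, while the sample labels number the control like the TRMT12 siRNA, so whether the control RNA was shared was not settled. No label says that hybridisations of an siRNA came from separate cultures, so the p-values for a single siRNA and for differences between siRNAs measure only the spread between hybridisations, which may be technical.

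Per the file headers and the values, the authors' image program gave for each spot the mean intensity of both channels above local background. A floor of 1 stood where no spot was found, and in a channel of some spots that were found. The program, the scanner and the genome build were not given in the sources used here. The same files held a calibrated ratio, which is the knockdown intensity over the control intensity divided by a single factor per array, as the authors deposited it. Those factors lay between 1.45 and 1.64 on the 6 arrays with the knockdown in Cy5 and were 0.785, 0.614 and 0.558 on the dye-swapped arrays of siRNA 1, 2 and 3. The files also held a spot quality, a fraction from 0 to 1 by the authors' program, and the spot area. A further deposited table held log2 ratios for the same arrays. Within a tolerance of 0.001 they equalled log2 of the calibrated ratio on the 6 arrays with the knockdown in Cy5, and minus that value on the 3 dye-swapped arrays. The medians of its columns were -0.0578, -0.103 and -0.154 for arrays 1 to 3 of siRNA 1, -0.258, -0.207 and -0.0438 for siRNA 2, and -0.103, 0.0421 and -0.0467 for siRNA 3. The series text states that the columns of the dye-swapped arrays had already been exchanged, so each ratio here is knockdown over control as the array files give it. The targeted gene was lower on all 9 arrays in that direction, and would have been higher on the 3 dye-swapped arrays with the signs of the deposited table.

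The array held 36288 spots, of which 960 were blank, leaving 35328 probes. A ratio was computed where the spot was found and both channels lay above the floor. Because the deposited intensities were already background-subtracted, no further background correction was made, which departs from the normexp correction planned for uncorrected values. Log2 ratios were normalised within each array by loess with limma 3.58.1 in R 4.3.3, with blank spots at weight 0, and no step was applied between arrays. A probe was kept when its signal exceeded 2 background standard deviations in at least 1 channel on at least 6 arrays. That held for 30691 probes, and 28259 of them had a ratio in both dye orientations of every siRNA and were tested. The other 2432 were detected but had no dye-balanced ratio for at least 1 siRNA.

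Gene names came from the platform annotation, updated to current symbols through the gene identifier, or else from the transcript accession in the array files, with the human gene table of assembly GRCh38.p14 used only for names. Of the 35328 probes, 21568 had a current symbol and 177 an old symbol from the platform annotation, 1943 were named through an accession, 1025 matched several genes, 372 had sources that differed, and 10243 had no name here. Probes with several genes or differing sources were left unnamed. The tested probes with a symbol numbered 19622 and covered 14069 genes. Of the 4155 genes with several tested probes, 40.1% had probes whose mean log2 ratios differed in sign, and 36 were called both higher and lower with siRNA 1. Counts are therefore counts of probes unless genes are named. A probe is called dim when its mean log2 intensity lies below 8.64, the median of the tested probes. The gene lists used the brightest probe of each gene. The current symbol of TRMT12 is TYW2, and the older name of the labels is kept here.

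Before the data were examined, the tests, the gene lists, the rule for naming genes and most alternatives were fixed. For the comparison across siRNAs, each siRNA gave a single value, the mean of its Cy5 average and its dye-swapped array, and the 3 values were tested against 0 with limma's moderated test. For single siRNAs and their differences, all 9 arrays were fitted together with a mean per siRNA and a dye term. The control RNA enters only through the ratios, so its own spread between cultures is left out. Benjamini-Hochberg adjusted p under 0.05 was the threshold throughout. An exact test that flips the signs of 3 values cannot give a two-sided p below 0.25.

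Genes were named by a fixed rule. TRMT12 was always named. Across the siRNAs, the rule took up to 12 genes each way past the threshold with the same sign on all arrays that gave a ratio. For each siRNA it took the 6 largest changes each way past the threshold with the same sign on those of its 3 arrays that gave a ratio, and for each difference between siRNAs the 4 largest each way. For each list it took the 2 highest and the 2 lowest members. Of the genes it names, 3 are not reported here. Because only TRMT12 passed across the siRNAs, a further set was chosen after the values were seen: the 12 largest mean changes each way among genes called the same way with every siRNA and with the same sign on every array that gave a ratio, from 464 genes that were higher and 514 that were lower.

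The 25 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with a correlation estimated from the data and with fry. Lists for single siRNAs used genes with a ratio on all 9 arrays. A shared control was simulated with no effect of any siRNA, assuming that control and knockdown samples vary alike.

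On simulated data with 200 of 28259 probes changed, the test across siRNAs recovered 0% of 1.5-fold, 51.5% of 2-fold and 86.5% of 4-fold changes. The test of siRNA 1 recovered 51%, 81.5% and 94%, and the difference between siRNA 2 and siRNA 1 recovered 30.5%, 68% and 88%. Over 14069 simulated genes, camera called 0 lists in 20 runs with no shift and called a list shifted by 0.3 in 20 of 20 runs. The simulated genes were independent of each other, so these runs do not test whether the preset correlation suits lists of correlated genes.

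The alternatives covered background correction, normalisation within and between arrays, the filter on dim probes, spot quality, the authors' calibrated ratios, the dye term, the unit of replication, array weights, thresholds, the probe chosen for a gene, and leaving out each array or siRNA in turn. Plain subtraction of the background is the setting used, so it was not run separately. Added after the data were seen were normexp with an offset of 50, arrays of a single dye orientation, the deposited table with its own signs, and leaving out probes printed next to a much brighter spot. With 9 arrays and 3 siRNAs, their number limits the precision. Figures were drawn with matplotlib 3.10.9.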

Results

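The data describe gene expression in SKbr3 cells after knockdown of TRMT12, the enzyme that adds the aminocarboxypropyl side chain during synthesis of wybutosine, a modified guanosine beside the anticodon of phenylalanine transfer RNA. There were 3 siRNAs against TRMT12, each compared with control siRNA on 3 arrays, and 1 array of each group had the dyes exchanged. Median spot signal above background lay between 273.2 and 518.9 in the knockdown channel and between 204.55 and 538.8 in the control channel. Between 2.57% of probes on array 3 of siRNA 3 and 24.4% on array 1 of siRNA 2 gave no ratio. The 28259 probes tested covered 14069 named genes.

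TRMT12 messenger RNA was lower on all 9 arrays. The mean log2 ratio of knockdown over control was -2.64 ± 0.0887 with siRNA 1, -2.53 ± 0.149 with siRNA 2 and -2.49 ± 0.129 with siRNA 3 (SD, n = 3 arrays each). The dye-adjusted estimates left 16.3%, 17.6% and 18.1% of the control level, with adjusted p of 5.12e-05, 6.84e-05 and 7.77e-05. Across the 3 siRNAs TRMT12 fell 5.78-fold, a mean log2 ratio of -2.53 (SE 0.0733, adjusted p = 0.00999). The depth of the knockdown was not shown to differ between siRNAs: siRNA 3 minus siRNA 1 was 0.16 (SE 0.0858, adjusted p = 0.329), siRNA 2 minus siRNA 1 was 0.11 (adjusted p = 0.507) and siRNA 3 minus siRNA 2 was 0.05 (adjusted p = 0.763). The call across the siRNAs ended without array 3 of siRNA 2 (-2.57, adjusted p = 0.0562), and other settings that ended it stand with the processing alternatives.

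**Figure D1:**
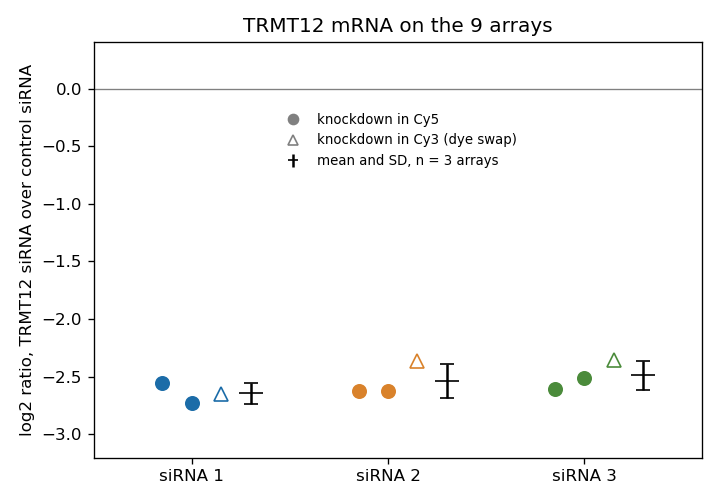
Log2 ratio of TRMT12 messenger RNA, TRMT12 siRNA over control siRNA, on each of the 9 arrays, with circles for the knockdown in Cy5, open triangles for the dye swap, and the mean and SD of 3 arrays beside them. Every array lay between -2.73 and -2.35.

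The question across siRNAs was which genes moved with TRMT12 whichever siRNA was used. Of 28259 probes, limma called 1, TRMT12 itself, while 6611 had an unadjusted p under 0.05 and 1679 an adjusted p under 0.1 (1016 higher, 663 lower). The simulation with no effect and a shared control called 0, with 4118 at an unadjusted p under 0.05. The count depended on the processing. Normexp with an offset of 50 called 1076, signal in both channels on all arrays 1589, and leaving out low-quality spots 1528. The authors' ratios and no background correction each called 0. Without array 2 of siRNA 2 the calls were 401, and without its array 3 they were 0, with 4455 at an unadjusted p under 0.05. Below that threshold, 913 probes (503 genes) were called higher and 729 (561 genes) lower with each siRNA taken separately. With median centring these were 191 and 324 probes, and with the authors' ratios 423 and 730. The mean over the siRNAs had a median of -0.0463 and -0.0233 over all tested probes in these scalings. The genes named next were chosen after their values were seen, and their adjusted p across siRNAs lay between 0.0823 and 0.185. Among those higher with every siRNA were SMG1, a kinase of nonsense-mediated decay (mean log2 ratio 1.46, SE 0.157), the zinc-finger genes ZNF652 (1.36, SE 0.186) and ZNF644 (1.21, SE 0.0767), and POLR3E, a subunit of RNA polymerase III (1.21, SE 0.177). CYCS, which encodes cytochrome c, had 1.20 (SE 0.16), the Polycomb gene PHC3 1.08, and the golgin GCC2 1.06. NPIPB4, CCDC186, CSGALNACT2, BPNT1 and BZW2 lay between 1.05 and 1.26.

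Genes lower with every siRNA included FASN, the fatty acid synthase (-0.89, SE 0.111), the desmosomal plaque gene EVPL (-0.89, SE 0.128), the mitochondrial aldehyde dehydrogenase ALDH2 (-0.85, SE 0.298), and ARID1A, a subunit of a chromatin remodelling complex (-0.82, SE 0.0768). The lysosomal protease CTSZ had -0.71 and the lamin LMNB2 -0.70. SLC38A12, MAB21L4, TMEM9B, EHBP1L1 and CALML5 lay between -0.93 and -0.69. Dim probes measured POLR3E, CCDC186, GCC2, BZW2, ARID1A, SLC38A12 and CALML5, and ARID1A and SLC38A12 had no ratio on 1 array. Several of these genes had a second probe that moved less. A brighter FASN probe had -0.27, the other SMG1 probe 0.83, and a brighter NPIPB4 probe 0.00 with adjusted p of 0.241, 0.553 and 0.718 for the 3 siRNAs. SMG1 and NPIPB4 belong to families with near-identical copies, so their signal cannot be assigned to a single copy here.

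**Figure D2:**
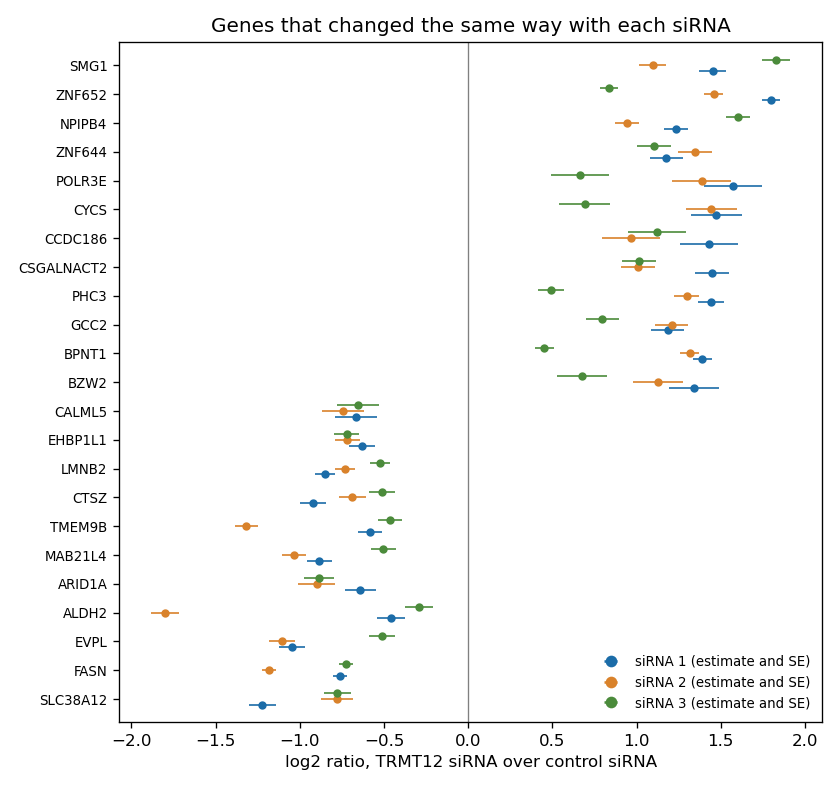
Log2 ratio of TRMT12 siRNA over control siRNA for the genes with the largest changes called the same way with each siRNA, with a point per siRNA and its SE from the 9-array fit. ALDH2 moved most with siRNA 2 (-1.80, against -0.46 and -0.29), while ZNF644 and EHBP1L1 had similar values with all 3.

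Among the 25 gene lists, 9 passed camera across the siRNAs, 7 higher and 2 lower. With an estimated correlation camera called 0 lists, 0 at an unadjusted p under 0.05, and each of the 9 had an adjusted p = 0.768. Fry called 0 lists and 4 at an unadjusted p under 0.05. Its lowest adjusted p was 0.0754, for the wybutosine list, which holds TRMT12 itself. The calls were therefore made only by camera with the preset correlation. With an estimated correlation, camera across the siRNAs takes its degrees of freedom from 3 values, so it can call little even for uncorrelated genes. Fatty acid synthesis genes, with an estimated correlation of -0.0238, went from p = 0.024 to p = 0.139 in camera. NF-kB and inflammatory genes rose most: all 14 measured members had a positive mean, with a list median of 0.52 (adjusted p = 9.74e-06), and 6 passed adjusted over the list alone. ICAM1, an adhesion molecule, had 1.01 (SE 0.171) and CXCL8, the neutrophil chemokine, 0.92 (SE 0.347), both at dim probes. The CXCL8 values were 1.89, 0.85 and 0.02 with siRNA 1, 2 and 3. NFKB2 and RELB had 0.12 and 0.06. Genes of the ATF4 and amino acid response rose with a median of 0.33 (20 of 22 positive, adjusted p = 0.00042), and adjusted over the list alone 9 passed, 7 higher and 2 lower. PPP1R15A, which restores translation after stress, had 0.79 (SE 0.186) and DDIT3, the transcription factor CHOP, 0.68 (SE 0.127). The list's lowest members were the amino acid transporter SLC7A5 (-0.45, SE 0.0708) and ATF5 (-0.39, SE 0.113).

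With the preset correlation, and with an estimated adjusted p = 0.768 for each list of this paragraph, 4 further lists were higher. ER chaperones and unfolded protein response genes had a median of 0.13 (17 of 18 positive, adjusted p = 0.00412). SEL1L, of ER-associated degradation, had 0.77 (SE 0.114) and DNAJB9 0.66 (SE 0.125), while SDF2L1 had 0.00 and XBP1 -0.17, and 6 members passed adjusted over the list alone. NRF2 and oxidative stress genes had a median of 0.14 (16 of 17 positive, adjusted p = 0.00758), with the haem oxygenase HMOX1 at 0.78 (SE 0.278), the cystine transporter SLC7A11 at 0.65 (SE 0.192) and AKR1B10 at 0.08. Heat shock genes had 0.15 (12 of 13 positive, adjusted p = 0.0144), led by the co-chaperone BAG3 at 0.60 and CRYAB at 0.35, with HSPE1 at 0.00 and HSPB1 at -0.12. ERBB and MAPK response genes had 0.16 (12 of 19 positive, adjusted p = 0.0481), with the immediate early genes EGR1 at 0.63 and FOS at 0.56 and with DUSP4 at -0.18 and ETV5 at -0.19. In the NRF2, heat shock and ERBB lists limma called 0 members adjusted over the list alone, with 4, 3 and 7 at an unadjusted p under 0.05. Over all 28259 probes 6611 had such a p, a share like that of the NRF2 and heat shock members. The heat shock call was lost with median centring (0.04, adjusted p = 0.127), and the NRF2 call on the Cy5 arrays alone (0.02, adjusted p = 0.757).

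Cytosolic ribosomal protein genes passed with a median of only 0.06 (47 of 53 positive, adjusted p = 0.0144, and 0.768 with an estimated correlation). Limma called 0 of these genes adjusted over the list alone or at an unadjusted p under 0.05. Their direction followed the dye: the list median was -0.29 on the arrays with the knockdown in Cy5 and 0.41 on the dye-swapped arrays. It turned to -0.04 with median centring and -0.02 with the authors' ratios, where all genes had medians of -0.07 and -0.04. The list thus stayed slightly above all genes there, but its call in camera was lost (adjusted p = 0.968 and 0.887). RPL17 and RPL5 had 0.17 and 0.16, and RPS2 and RPS15A -0.11 and -0.15.

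Cell cycle lists were lower with the preset correlation (estimated adjusted p = 0.768 for both), and neither passed with siRNA 3 alone. G1/S and DNA replication genes had a median of -0.18 (27 of 29 negative, adjusted p = 1.59e-05), and 8 passed adjusted over the list alone, all lower. CCNE1, the cyclin E that drives S-phase entry, had -0.52 (SE 0.104). E2F1 had -0.58 (SE 0.233), with values of -0.32, 0.14 and -1.55 at a dim probe, and GINS1 and SLBP had 0.16 and 0.03. G2/M and mitosis genes had a median of -0.21 (25 of 30 negative, adjusted p = 0.000538). The ubiquitin-conjugating enzyme UBE2C had -0.45 (SE 0.0675) and the kinesin KIF2C -0.42 (SE 0.0814), 2 of the 3 members that passed adjusted over the list alone, while CENPE and HMMR had 0.28 and 0.25.

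**Figure D3:**
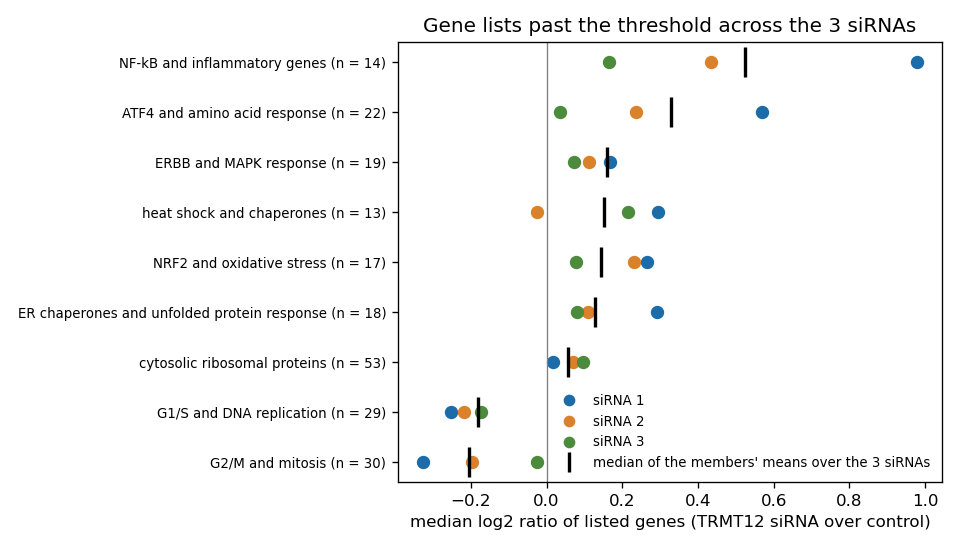
Median log2 ratio, TRMT12 siRNA over control siRNA, of the listed genes for each siRNA (coloured points) and of their means over the 3 siRNAs (black bars), for the 9 lists past the threshold, with the number of genes beside each name. NF-kB genes had 0.98, 0.43 and 0.17 with siRNA 1, 2 and 3. The ribosomal protein list median lay below 0 under median centring and the authors' ratios, as did that of all genes, and its call was lost.

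Within the wybutosine pathway itself, 5 of 6 measured genes, TRMT12 among them, passed adjusted over the list alone, although the list as a whole did not pass (median -0.08, adjusted p = 0.537). TYW3, the methyltransferase that acts after TRMT12 in the pathway, was higher on all 9 arrays, with a mean of 0.63 (SE 0.0728, adjusted p over the list alone = 0.000986) and 0.62, 0.74 and 0.53 with the 3 siRNAs. TYW5, a hydroxylase, had 0.23 (SE 0.0691), and LCMT2, another methyltransferase of the pathway, -0.27 (SE 0.0676). Other tRNA modification enzymes did not pass as a group (median 0.02, adjusted p = 0.495), with TRMT13 and TRMT11 at 0.46 and 0.31 and GTPBP3 and WDR4 at -0.27 and -0.26. Nor did cytosolic aminoacyl-tRNA synthetases pass (0.09, adjusted p = 0.432), with SARS1 and TARS1 at 0.26 and 0.24 and VARS1 and QARS1 at -0.32 and -0.15. Translation factors had 0.05 (adjusted p = 0.238), with EIF2S1 and EIF4A2 at 0.39 and 0.37 and EIF4G1 and EIF4H at -0.39 and -0.29.

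Lipid and mitochondrial lists did not pass. Fatty acid synthesis genes had a median of -0.17 (10 of 14 negative, adjusted p = 0.0601), and 3 passed adjusted over the list alone, among them the lipogenic regulator SREBF1 at -0.42 and the citrate carrier SLC25A1 at -0.32. THRSP had 0.40 (SE 0.545) and ACSL1 0.19. Cholesterol synthesis genes had a median of -0.04 and a mean of 0.00 (adjusted p = 0.864), with STARD4 at 0.64, HMGCS1 at 0.35, DHCR7 at -0.36 and MVK at -0.38. Oxidative phosphorylation genes had -0.03 (adjusted p = 0.259), with CYCS at 1.20, NDUFA5 at 0.28, NDUFA10 at -0.31 and ATP5F1D at -0.38. Hypoxia and glycolysis genes had 0.06 (adjusted p = 0.47), with BNIP3L and CA9 at 0.33 and 0.25 and PFKFB4 and NDRG1 at -0.33 and -0.31.

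Stress and identity lists outside those named gave no call. Interferon-stimulated genes had 0.03 (adjusted p = 0.47), with RIGI at 0.55, IFI27 at 0.43, OAS3 at -0.38 and IFIT2 at -0.40. The p53 targets had 0.03 (adjusted p = 0.537), with GDF15 and BBC3 at 0.48 and 0.42 and FDXR and ZMAT3 at -0.37 and -0.35. Luminal epithelial markers had -0.07 (adjusted p = 0.47), although GATA3, a luminal transcription factor, had -0.53 (SE 0.0638) with -0.53 for each siRNA (adjusted p over the list alone = 0.00761). FOXA1 had -0.32 and AGR2 0.32. Genes of the ERBB2 amplicon had -0.14 (adjusted p = 0.125), with MED1 and PPP1R1B at 0.27 and 0.15 and CDK12 and IKZF3 at -0.56 and -0.30. The 8q24 neighbours of TRMT12 had 0.08 (adjusted p = 0.238), with ZHX1 and MYC at 0.39 and 0.34 and ZHX2 and WASHC5 at -0.32 and -0.21.

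Basal and mesenchymal markers had a median of 0.03 and a mean of -0.02, so that median and test differed in direction (adjusted p = 0.977), with KRT17 and ZEB2 at 0.18 and 0.14 and FN1 and LGALS1 at -0.32 and -0.22. Stromal and blood cell markers had 0.04 (adjusted p = 0.73), with VWF and LYZ at 0.30 and 0.25 and PDGFRB and COL1A1 at -0.26 and -0.22. The RNA interference machinery had -0.11 (adjusted p = 0.434), with AGO3 and AGO2 at 0.27 and 0.25 and GEMIN4 and TNRC6C at -0.42 and -0.24.

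With siRNA 1, 6467 probes were called, 3284 higher and 3183 lower, of which 800 and 229 moved at least 1.5-fold. Leaving out 1 array gave between 2289 and 8041. The simulation with no effect and a shared control, which takes every difference between siRNAs as spread between samples, called 6032, 5870 and 5928 for siRNA 1, 2 and 3. It added technical error to the value of each siRNA and again to each array, which raises these counts. With median centring the split was 1538 higher and 3472 lower, and with the authors' ratios 2306 and 3647. The median of all tested probes with siRNA 1 was -0.0328 and 0.021 in these scalings. The ATF4 list rose with a median of 0.57 and 19 of 22 members called higher (adjusted p = 9.05e-12, and 0.0123 with an estimated correlation). NF-kB genes rose with a median of 0.98 and 10 of 14 called (adjusted p = 2.08e-08, and 0.0141 estimated). G2/M genes fell by 0.33 with 25 of 30 called lower (adjusted p = 7e-10, and 0.0141 estimated), and G1/S genes fell by 0.25 with 15 of 29 called (adjusted p = 5.81e-06, and 0.0169 estimated). Heat shock genes rose by 0.29 (adjusted p = 9.88e-05, and 0.0393 estimated). ER chaperone (0.29), NRF2 (0.26), interferon (0.19), ERBB (0.17) and aminoacyl-tRNA synthetase genes (0.20) rose, and fatty acid (-0.20) and oxidative phosphorylation genes (-0.10) fell, with the preset correlation alone, the estimated adjusted p lying between 0.0626 and 0.191. The largest rises by the naming rule were IL1RL1, the receptor of interleukin 33 (2.14, SE 0.0804, adjusted p = 9.37e-05), SLC7A11 (2.08, SE 0.365) and CXCL8 (2.01, SE 0.295), besides RGPD5, MITF and HOXA9 (2.45, 2.15 and 2.04, the last 2 measured on 2 arrays), all 6 at dim probes. HOXA9 also had a dye term of 1.67 (limma adjusted p = 0.0142). With siRNA 1 a brighter second probe had 0.11 for IL1RL1 and 1.18 for SLC7A11. With it 3 other MITF probes lay between -0.10 and 0.34, and 2 other RGPD5 probes had 0.69 and 0.35. After TRMT12, the largest falls by the naming rule were COL5A2, a fibrillar collagen (-1.56, SE 0.0951), the G-protein regulator RGS3 (-1.55), LIMD2 (-1.38), SLC38A12 (-1.22) and MDFIC (-1.22), all but MDFIC at dim probes.

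With siRNA 2, 5720 probes were called, 2967 higher and 2753 lower, of which 541 and 291 moved at least 1.5-fold. With the authors' ratios 1481 and 2238 were called, where the median of all tested probes was -0.0675. Leaving out 1 array gave between 3483 and 4883. The simulation with no effect called 5870, a count raised in the same way. The ATF4 list rose by 0.24 (12 of 22 called higher, adjusted p = 2.76e-05, and 0.0388 with an estimated correlation) and G1/S genes fell by 0.22 (13 of 29 called lower, adjusted p = 2.76e-05, and 0.0388 estimated). NF-kB genes rose by 0.43 (4 of 14 called, adjusted p = 0.00459, and 0.112 estimated) and G2/M genes fell by 0.20 (15 of 30 called, adjusted p = 0.000384, and 0.112 estimated). NRF2 genes rose by 0.23 (adjusted p = 0.000384, and 0.275 estimated), fatty acid genes fell by 0.27 (adjusted p = 0.0342, and 0.206 estimated), and ribosomal protein genes had 0.07 (adjusted p = 0.00454, and 0.724 estimated). The largest falls by the naming rule after TRMT12 were ALDH2 (-1.80, SE 0.0819, adjusted p = 0.00021), DLD, a subunit shared by the mitochondrial keto-acid dehydrogenases (-1.69, SE 0.0692), and the glyoxalase GLO1 (-1.52, SE 0.0546), together with the fibulin EFEMP1 (-1.64, SE 0.0489). LAMB4 had -1.41 at a dim spot printed next to the bright DLD spot. The largest rises named here, from HYCC1 (2.47) through RABGAP1, HOXA9 (1.99) and NXPE3 (1.77) to NEDD4 (1.64), were all at dim probes. HYCC1, HOXA9 and NEDD4 were measured on 2 arrays. The dye term was 1.67 for HOXA9 and 1.07 for HYCC1 (limma adjusted p = 0.0142 and 0.0646). For RABGAP1, 3 other probes lay between -0.11 and 0.12.

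With siRNA 3, 5656 probes were called, 2799 higher and 2857 lower, of which 347 and 153 moved at least 1.5-fold. Leaving out 1 array gave between 2252 and 6832. With median centring the split was 806 and 2525, and with the authors' ratios 1475 and 3084. The median of all tested probes with siRNA 3 was -0.0191 and 0.0118 in these scalings. The simulation with no effect called 5928, a count raised by technical error added to the siRNA value and again to each array. NF-kB, ATF4, G1/S and G2/M lists did not pass with this siRNA (medians 0.17, 0.04, -0.17 and -0.03, adjusted p = 0.113, 0.67, 0.0697 and 0.693), and heat shock genes passed only with the preset correlation (0.21, adjusted p = 0.0462, and 0.243 estimated). The largest rises by the naming rule were SMG1 (1.83, SE 0.0818), NPIPB4 (1.60, SE 0.0714), the nuclear cyclophilin PPIG (1.28), the kinase STK38L (1.20), the tight junction protein CLDN1 (1.18, SE 0.0499, adjusted p = 0.000314) and WIPF1 (1.16). The largest falls by that rule after TRMT12 were VCP, an ATPase of protein degradation (-1.08, SE 0.045, adjusted p = 0.000314), TNNT1 (-1.06), RIBC2 (-0.99), PPIF, the mitochondrial cyclophilin (-0.98, SE 0.056), and the semaphorin SEMA3B (-0.97). Those of STK38L, WIPF1, TNNT1, RIBC2 and SEMA3B were at dim probes. VCP and PPIF had 0.07 and -0.07 with siRNA 1.

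The siRNAs also differed from each other where the difference itself was tested. Between siRNA 2 and siRNA 1, 740 probes differed (285 higher and 455 lower with siRNA 2). MDFIC (1.61), the pyruvate dehydrogenase subunit PDHX (1.08), COL5A2 (1.07) and CMBL (1.05) were higher with siRNA 2, and DLD (-1.72, SE 0.0958), EFEMP1 (-1.66), the osmotic stress factor NFAT5 (-1.55) and LAMB4 (-1.44) lower. Between siRNA 3 and siRNA 1, 2618 differed (1208 and 1410), with COL5A2 (1.67), MDFIC (1.54), the calcium pump ATP2B4 (1.48) and PDHX (1.46) higher and RGPD5 (-2.43), CXCL8 (-2.12), the inflammatory caspase CASP4 (-1.97) and IL1RL1 (-1.87, SE 0.111, adjusted p = 0.00259) lower with siRNA 3. Between siRNA 3 and siRNA 2, 2875 differed (1503 and 1372), with EFEMP1 (2.06), DLD (1.92), the ectonucleotidase NT5E (1.82) and LAMB4 (1.75) higher and the uridylyltransferase TUT4 (-1.86), NCOA7 (-1.47), the splicing factor SREK1 (-1.30) and DDC (-1.24) lower with siRNA 3. Of these genes, COL5A2, NFAT5, LAMB4, ATP2B4, RGPD5, CXCL8, CASP4, IL1RL1, TUT4, NCOA7 and DDC were measured at dim probes. With median centring these counts dropped to 12, 67 and 61. Leaving out an array brought them to 40 (array 3 of siRNA 1), 317 and 556 (array 1 of siRNA 3) at the lowest.

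Stress and cell cycle lists also differed between siRNAs. ATF4 genes were lower with siRNA 2 than with siRNA 1 by a median of 0.33 (adjusted p = 1.54e-08, and 0.026 with an estimated correlation) and lower with siRNA 3 than with siRNA 1 by 0.57 (adjusted p = 2.1e-13, and 0.00903 estimated). NF-kB genes differed by -0.80 between siRNA 3 and siRNA 1 (adjusted p = 1.69e-06, and 0.0232 estimated), G2/M genes by 0.32 (adjusted p = 1.5e-08, and 0.0232 estimated) and cholesterol synthesis genes by 0.33 (adjusted p = 3.03e-05, and 0.0276 estimated). Between siRNA 3 and siRNA 2 the differences were -0.28 for NRF2 genes (adjusted p = 0.00034, and 0.253 estimated), -0.20 for ATF4, 0.18 for G2/M and 0.21 for cholesterol synthesis genes (adjusted p = 0.00243 each, and 0.142, 0.166 and 0.142 estimated) and 0.14 for heat shock genes (adjusted p = 0.0487, and 0.253 estimated). With the preset correlation alone, siRNA 3 also differed from siRNA 1 for NRF2 (-0.38), interferon (-0.26), ERBB (-0.25), ER chaperone (-0.20), p53 (-0.14), G1/S (0.11) and oxidative phosphorylation genes (0.11), with estimated adjusted p from 0.0697 to 0.362. In the same way siRNA 2 differed from siRNA 1 for NF-kB (-0.40), heat shock (-0.28), interferon (-0.24), ER chaperone (-0.21), aminoacyl-tRNA synthetase (-0.18), p53 (-0.13), ERBB (-0.07), hypoxia (-0.04), ribosomal protein (0.03), oxidative phosphorylation (0.11) and G2/M genes (0.15), with estimated adjusted p from 0.0534 to 0.706. With median centring the siRNA 3 minus siRNA 1 medians were -0.55, -0.79, 0.34 and 0.36 for ATF4, NF-kB, G2/M and cholesterol synthesis genes and passed with the preset correlation, but the estimated adjusted p was 0.389, 0.151, 0.595 and 0.688. With the authors' ratios it was 0.172, 0.111, 0.26 and 0.365. The ATF4 difference between siRNA 2 and siRNA 1 was -0.20 with median centring and -0.27 with the authors' ratios, where the estimated adjusted p was 0.795 and 0.486.

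The changes of the siRNAs correlated across probes, which are not independent replicates. Pearson's r was 0.448 between siRNA 1 and siRNA 2, 0.455 between 1 and 3, and 0.347 between 2 and 3, where unchanged groups simulated against a shared control gave 0.311, 0.301 and 0.287. The mean r of 0.417 was 0.3002 with median centring and 0.3005 with the authors' ratios, near those simulated values, and the simulation was not run for these scalings. The covariance exceeded the simulated one by 0.0164, 0.00437 and 0.00167. The 913 and 729 probes called higher and lower with each siRNA compare with 34.2 and 31.4 for independent lists and with 645 and 578 in that simulation. Those simulated counts are raised, because technical error was added to the siRNA value and again to each array. Controls could not be split here, so part of the excess over independent lists may come from a shared control.

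The dye term was past the threshold for 8264 probes (4111 higher, 4153 lower with the knockdown in Cy5; 3351 and 1631 with median centring). Over the brighter probes, arrays of the same siRNA correlated at 0.754 to 0.899 in the same orientation and at 0.415 to 0.524 in opposite orientations. Arrays of different siRNAs gave 0.427 to 0.715 in the same orientation and 0.0852 to 0.311 in opposite orientations. Over all probes the same siRNA gave 0.0354 to 0.203 in opposite orientations, and different siRNAs 0.273 to 0.617 in the same and -0.0899 to 0.0904 in opposite orientations.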

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

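The tests of the stress and cell cycle lists and of neighbouring spots were chosen after the result was seen, and those of other probes and of other splits before.

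Some results differed between the siRNAs or came from data outside the comparisons. Differences between siRNAs past the threshold numbered 740 probes for siRNA 2 against siRNA 1, 2618 for siRNA 3 against siRNA 1 and 2875 for siRNA 3 against siRNA 2. With loess values and an estimated correlation, list medians differed for ATF4 genes by -0.33 (siRNA 2 minus siRNA 1; -0.20 with median centring, estimated adjusted p = 0.795) and -0.57 (siRNA 3 minus siRNA 1), and between siRNA 3 and siRNA 1 for NF-kB genes by -0.80, G2/M genes by 0.32 and cholesterol synthesis genes by 0.33. With median centring the siRNA 3 minus siRNA 1 differences did not pass with an estimated correlation (camera adjusted p = 0.389, 0.151, 0.595 and 0.688). Nor did they with the authors' ratios (0.172, 0.111, 0.26 and 0.365). Of 960 blank spots, which no comparison uses, 1 lay above background on at least 6 arrays. Outlying arrays were not tested within groups of 3, but in the 9-array fit array 2 of siRNA 2 had the lowest quality weight, 0.268, and without it 401 probes were called across the siRNAs.

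Other splits of the arrays were too few for a share under 0.05. Of the 4 ways of turning signs, 1, the real one, gave 1 call across the siRNAs and 6467, 5720 and 5656 for siRNA 1, 2 and 3, and the highest other gave 0 each time. Of 10 splits of the 6 arrays of a pair of siRNAs, 1, the real one, gave 740, 2618 and 2875 differences, and the highest others gave 86, 55 and 0.

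ATF4 and NF-kB genes were higher and G1/S and G2/M genes lower across the siRNAs with the preset correlation, not with an estimated one (adjusted p = 0.768 each) or fry, and none of the 4 lists passed with siRNA 3 alone. A dye effect left in the averages is argued against, since the smallest of the 4 list medians in either orientation, in the direction of the pattern, was 0.178, and all passed. The loess normalisation is argued against as the whole cause, since with median centring and the authors' ratios the smallest was 0.227. A control RNA that stood apart and was common to the siRNAs stays open: the smallest median for a single siRNA was 0.0258 (G2/M with siRNA 3), still in the direction of the pattern. An effect of losing TRMT12 may also stand behind it and was not tested apart from that.

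The ATF4, NF-kB and G2/M lists moved further with siRNA 1 than with siRNA 3. A common control predicts equal shifts, and the highest estimated-correlation adjusted p of the 3 differences was 0.0232 with loess, while with median centring the differences were as large (-0.55, -0.79 and 0.34) but had 0.389, 0.151 and 0.595, the estimated correlations being higher there (0.462, 0.048 and 0.561, against -0.0246, -0.0286 and 0.0166). Shifts in proportion to the fall of TRMT12 predict equal ratios, and the fall with siRNA 3 was 94.0% of that with siRNA 1, while the ATF4, NF-kB and G2/M shifts were 6.20%, 16.9% and 7.88%. Neither explanation is excluded, because these p-values measure the spread between hybridisations, which may be technical, and spread between cultures could give unequal shifts from either. Effects of siRNA 1 on other transcripts and separate control samples for each siRNA stay open too and were not tested.

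Dim probes changed with the spot printed in the preceding column when that spot was at least 16-fold brighter. Over 1817 such probes the difference between siRNA 3 and siRNA 2 correlated with that of the brighter neighbour at 0.235, above all 1000 shuffles (highest 0.0779), and at 0.119 with the column before that. Related genes printed side by side are argued against, since the correlation with the following column was 0.0462. Signal carried from a spot to the next column may therefore add to dim probes. Probes after such a spot, dim or not, were still called less often with siRNA 2 (10.7% of 2402) than the others (21.1%). Among the dim probes that may be affected was LAMB4, with a dye-balanced average of -1.34 with siRNA 2 after DLD with -1.66. Of 5 other named genes after a brighter spot, in the same averages, MDFIC (-1.21, 0.38 and 0.31, neighbour -0.18, -0.34 and -0.18), SREK1 (0.81, 0.74 and -0.50, neighbour -0.07, -0.18 and -0.13) and CALML5 (-0.75, -0.69 and -0.63, neighbour -0.01, 0.10 and 0.09) did not track it, RGS3 shared its sign alone, and TUT4 did so with siRNA 1 and 2; MDFIC and SREK1 are not dim.

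Rises of at least 2-fold at dim probes were checked against other probes of the same genes. Pairs of a risen probe and another probe of its gene were taken over the siRNAs together. In 25 of 80 pairs (31.2%) the other probe was called higher, against 10.7% of all probes (1-sided Fisher p = 5.07e-07). That test takes the pairs as independent, but a probe can recur with several siRNAs and beside several risen probes, so its p may be too low. The higher share argues against a signal specific to the probe as the whole cause, but the strength of that evidence was not settled. For bright rises the share was 61.9% (26 of 42 pairs), above that of dim rises (Fisher p = 0.00183, with the same limit). Part of the dim rises may therefore belong to the probe, as for RABGAP1 and MITF. No biological explanation was tested.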

How the results depend on the processing

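Normexp with an offset of 50, arrays of a single orientation, the deposited table with its own signs and leaving out probes after a brighter spot were chosen after the data were seen. Of the values for single genes and lists under all alternatives, 2462 kept direction and side of the threshold, 181 passed it newly, 192 no longer passed, 49 moved and 9 reversed. The cause was not tested unless given. Aquantile and no filter on dim probes moved nothing and say nothing about stability.

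TRMT12 was lower under every alternative, between -2.69 and -0.88. Its call across siRNAs was lost without background correction (-1.57, adjusted p = 0.0561), with the authors' ratios (-2.60, 0.0532), without siRNA 1 (-2.47, 0.278) or siRNA 3 (-2.57, 0.141), where fewer values were left, and with the deposited signs (-0.88, 0.0976), where 3 arrays are turned. In those settings limma called 0 probes across siRNAs, with 6427, 5785, 3615, 5759 and 7862 at an unadjusted p under 0.05.

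Across siRNAs, normexp with an offset of 50 called 1076 probes, scale normalisation 2, signal in both channels on all arrays (21395 probes) 1589, good spots alone (20980 probes) 1528, the siRNA as a random block 3533, independent arrays 6428, trend with robust moderation 873, dye-swapped arrays 5006, and adjusted p under 0.1 1679. Without background correction the dye term called 12600 and the differences 2 minus 1, 3 minus 1 and 3 minus 2 called 2427, 5071 and 4601. Median centring called 2210 for siRNA 2, 3331 for siRNA 3, 4982 for the dye, 12, 67 and 61 differences and 515 shared by all siRNAs. The authors' ratios called 3719 for siRNA 2, 5406 for the dye and 103, 674 and 981 differences. Good spots gave 2080, 4440 and 4557 differences, and both channels 1667 and array weights 1365 for 2 minus 1. No dye term gave 3387, 2559 and 2656 for siRNA 1 to 3, 72, 403 and 460 differences and 624 shared. An siRNA's own 3 arrays, a smaller sample fitted without a dye term, gave 0, 0 and 0 in limma. At an unadjusted p under 0.05 they gave 6478, 3607 and 5951.

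Adjusted p under 0.1 gave 1819, 4302 and 4578 differences, and under 0.01 86, 389 and 511, with 3196, 2316 and 2641 for the siRNAs and 2836 for the dye. At least 1.5-fold gave 1029, 832 and 500 for the siRNAs, 276 for the dye and 245, 552 and 612 differences. The mean correlation between siRNAs (0.417) was 0.541 without background correction, 0.478 with normexp 50, 0.3002 with median centring and 0.3005 with the authors' ratios, 0.523 with both channels, 0.527 with good spots, 0.582 on dye-swapped arrays and 0.480 with deposited signs.

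The number of lists (9) was 5 with plain means, 4 without siRNA 1, 3 with deposited signs, and 0 with the estimated correlation and 0 with fry. Ribosomal protein genes (0.0572) reversed with median centring (-0.0387), the authors' ratios (-0.0155), plain means (-0.0553), Cy5 arrays alone (-0.29), deposited signs (-0.52) and without array 3 of any siRNA (leaving out an array or siRNA gave -0.0698 to 0.0784). With median centring and the authors' ratios the ribosomal list median still lay above that of all genes (-0.0668 and -0.0438). NRF2 genes reversed with deposited signs (-0.10). Heat shock genes lost their call in 12 alternatives, NRF2 in 7, ERBB response in 16, ER chaperones in 5, G2/M in 4, G1/S and NF-kB in 3 and ATF4 in 2, and fatty acid genes passed in 11. ER chaperones (0.07, adjusted p = 0.129) and G2/M (-0.11, 0.0894) lost theirs without siRNA 1.

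Leaving out each array gave 0 (without siRNA 2 array 3, with 4455 at an unadjusted p under 0.05) to 401 (without siRNA 2 array 2) calls across siRNAs, 2289 (without siRNA 1 array 3) to 8041 for siRNA 1, 3483 to 4883 for siRNA 2, 2252 (without siRNA 3 array 3) to 6832 for siRNA 3, and 3276 to 9381 for the dye. Differences ranged from 40 (without siRNA 1 array 3) to 595, 317 to 3568 and 556 to 2377 (both lowest without siRNA 3 array 1), shared calls from 751 to 1687, lists from 5 (without array 3 of siRNA 1 or 3) to 10, correlation from 0.341 to 0.463, and TRMT12 from -2.57 (adjusted p = 0.0562, without siRNA 2 array 3) to -2.52. Where an orientation was left with no array, that siRNA's dye effect stayed in its value.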

Other observations

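The grouping of genes by the letters that open their symbol was chosen after the data were seen. Of 92 such groups with at least 15 genes, only the zinc-finger genes named ZNF passed camera with the preset correlation: 249 of 374 had a positive mean, with a median log2 ratio of 0.08 (adjusted p = 0.00131) and 0.05, 0.09 and 0.08 with siRNA 1, 2 and 3. With an estimated correlation they did not pass in camera (p = 0.0466, adjusted p = 0.978), although that correlation, 0.0093, lay below the preset 0.01. This test takes its degrees of freedom from the 3 siRNA values, so a higher correlation is not what ended the call. Among the ZNF genes 81, 90 and 77 were called higher and 23, 19 and 15 lower with the 3 siRNAs. The median stayed positive in every setting tried: 0.07 and 0.09 in the Cy5 and dye-swapped orientations, 0.05 with median centring, 0.07 with the authors' ratios and 0.03 without background correction.

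Some list members outside the naming rule were picked for their high values after these were seen. HSPA5, the main ER chaperone, had 0.47, the ATF4 targets ATF3 and SESN2 0.57 and 0.51, and the NF-kB targets IL6, TNFAIP3 and NFKBIA 0.69, 0.48 and 0.40. None of them passed across the siRNAs over all genes.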
